A study of Sus scrofa with 21 samples.

How the data were processed

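The series holds bulk RNA sequencing of 21 libraries from 3 pigs (Sus scrofa): 10 from a microbrush, 4 from a bare Nitinol wire, 4 from surgically removed aorta and 3 from whole blood. Per the labels, total RNA was extracted with the RNAdvance Tissue kit in reduced volumes and made into libraries with SMARTer Pico. Per the submitters' processing notes, Salmon quantified the reads, DESeq2 was used, and the genome build was Sscrofa11.1; versions, annotation release and trimming are not stated. The values analysed were the estimated counts per Ensembl gene deposited by the authors, merged over the samples and not scaled between them. The table held 24358 genes, of which 14692 had a symbol in the supplied list of gene names and 9666 were left under their identifiers; the files gave no coordinates for them. In all, 11.9% of the values were not whole, and counts were rounded to whole numbers before the tests.

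Groups, pigs and organs were taken from the labels. Each comparison was fitted on its own libraries with edgeR 4.0.16 in R 4.3.3: genes were kept by filterByExpr with a minimum count of 10, libraries were scaled by TMM, and the quasi-likelihood test with robust dispersions was read at a Benjamini-Hochberg adjusted p under 0.05. Fold changes are log2, and levels are mean CPM after TMM scaling within the comparison, so the level of a gene in a group moves with the comparison. Scores, and the levels in the closing observations, come from TMM scaling over all 21 libraries instead. In that scaling blood 2 had a factor of 35.1, where the next highest was 1.86 (microbrush 3). Comparisons with blood include this library, so their levels should not be set beside those of other comparisons. The interaction fit held device, organ and their product. For 21 lists of cell types and responses with 447 members, fixed before the data were examined, limma 3.58.1 tested each list with camera on voom values at a preset correlation of 0.01, with an estimated correlation and with fry beside it. Members were counted over all genes tested and adjusted over the list alone. Some members stand on more than 1 list, such as MYL9 on the smooth muscle and platelet lists and SELP on the platelet and activation lists.

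For each library 4 measures were computed: the endothelial score with a pseudocount of 1, the percent of counts in 4 haemoglobin genes, the likeness to aorta over blood, and the genes detected after thinning to 1000000 counts with vegan 2.7.1. Blood 2 was left out of the last because its total lay under 100000 counts. Brush and wire libraries were compared by exact two-sided permutation tests over all 1001 splits, and within pig and organ. Wilson 95% intervals were computed for shares of single libraries, and a count of 0 was given a limit of 3 counts, scaled by TMM where a fold is given.

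Genes were named by a rule set before the data were examined: per comparison the 8 genes with the largest fold change in each direction among those with a symbol, an adjusted p under 0.05 and at least 10 CPM in the higher group, or the 4 smallest p-values per direction where none passed; a fixed set of markers (VWF and UMOD were on it but not in the table under those symbols); and up to 4 members with the smallest p per list. The test was also run on simulated counts with 200 changed genes per comparison at folds of 4, 16 and 64. Changed genes were drawn from those with a mean of at least 10 CPM. All simulated libraries of a comparison shared a pooled profile, so none lacked genes as some real libraries did.

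Alternatives covered RLE scaling, haemoglobin genes left out, no filter and a minimum count of 50, DESeq2 1.42.0, limma voom with quality weights, an adjusted p under 0.01, all libraries in a common fit, the pig as a replicate block, counts summed per pig, each organ and each pig alone, and each replicate left out in turn in groups of 2 to 5. The run without libraries under 5000 detected genes, the measures in each pig and organ alone, the likeness with a blood profile without blood 2, and the share without 2 abundant unnamed identifiers were chosen after seeing the data. Other splits of the libraries were drawn up to 100 per comparison. No library was left out of the main comparisons, and no pair of libraries within a group was a copy of another; pairs across groups were not checked.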

Results

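RNA was sequenced from 21 libraries of 3 pigs. The series concerned a microbrush that is passed through a blood vessel to pick up endothelial cells, the cells that line vessels. The microbrush gave 10 libraries, 5 from the kidney and 5 from the liver, and a bare Nitinol wire without a brush gave 4 libraries as the negative control, 2 per organ. Surgically removed aorta gave 4 libraries as the positive control, and whole blood gave 3 libraries. Pigs 243K and 248K each gave 5 microbrush and 2 wire libraries, with 2 blood libraries from pig 243K and 1 from pig 248K, while all 4 aorta libraries came from pig 237053. Total counts ran from 1144932 to 10188552 in the microbrush libraries and from 1946286 to 11128400 in the wire libraries. They ran from 1603229 to 3033008 in the aorta libraries and from 5634 to 5301288 in the blood libraries. Blood 2 held only 5634 counts over 302 genes, and microbrush 4 had counts for 3831 genes, against a microbrush mean of 16353 ± 4992 genes (SD, n = 10). The identifiers ENSSSCG00000018063 and ENSSSCG00000018061, to which the files give no name, together took 19.1% ± 17.1 of the counts in the microbrush libraries (SD, n = 10) and 35.9% ± 9.64 in the wire libraries (n = 4). Their share was 6.82% ± 1.52 in the aorta libraries (n = 4) and 3.57% ± 3.25 in the blood libraries (n = 3). Libraries from the same pig are not separate animals, so the p-values of single genes and of permutation tests below measure the spread between libraries. Camera at its preset correlation of 0.01 sets a list's genes against all other genes, and its p-values do not measure that spread alone. The correlation estimated from the data was higher, such as 0.682 for smooth muscle and 0.553 for matrix genes in brush against wire.

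The comparison of the microbrush with the bare wire asked what the brush collected beyond a wire in the same vessels. Smooth muscle genes, which encode the contractile apparatus of the vessel wall, had positive fold changes toward the brush in 21 of 22 measured members. Their median was 3.40 (log2), but 0 passed over all genes. With an estimated correlation the list had a camera adjusted p of 0.615. MYH11, the smooth muscle myosin heavy chain, averaged 21360 ± 27160 counts per 1000000 (CPM; SD, n = 10) on the brush and 319.9 ± 360.8 CPM (n = 4) on the wire. ACTA2, smooth muscle actin, averaged 3166 ± 4506 against 64.2 ± 51.1 CPM. Matrix genes of fibroblasts and the vessel wall had positive fold changes in 18 of 19 members, with a median of 2.49, and the fibrillar collagen COL1A1 averaged 4859 ± 8081 against 63.0 ± 72.5 CPM. Red cell genes lay the other way. HBB, the beta chain of haemoglobin, averaged 1143 ± 1393 CPM on the brush and 15620 ± 15370 CPM on the wire. ALAS2, the first enzyme of haem synthesis in red cell precursors, averaged 69.3 ± 69.2 against 637.3 ± 524.9 CPM.

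Of 16439 genes, 0 passed edgeR's test at an adjusted p under 0.05, with a smallest adjusted p of 0.392. An unadjusted p under 0.05 was found for 518, 437 of them higher on the brush. DESeq2 called 96 genes higher and 5 lower on the brush, and limma voom called 0. By edgeR the log2 fold change was 6.06 (SE 1.70, adjusted p = 0.502) for MYH11 and 5.62 (SE 1.73, adjusted p = 0.628) for ACTA2. It was 6.27 (SE 1.63, adjusted p = 0.436) for COL1A1 and -3.77 (SE 0.96, adjusted p = 0.392) for HBB. The smallest p-values toward the brush belonged to WFDC1 (7.91, SE 1.91), PDGFRB, a receptor of pericytes and smooth muscle (6.21, SE 1.54), FIBIN (7.30, SE 1.85) and ITGA7, a laminin receptor of muscle (6.68, SE 1.68). Those toward the wire belonged to SNCG (-2.86, SE 0.70), DMTN, a protein of the red cell membrane skeleton (-3.66, SE 0.91), ALAS2 (-3.20, SE 0.80) and HBB. The pig 248K libraries alone gave 46 genes and those of pig 243K alone 0, and a fit with the pig as a block gave 0. Wires 2 and 3, which had the fewest genes at fixed depth among the wires, were both of pig 248K. Pig and wire library therefore cannot be told apart in these counts. Counts summed per pig, with the pig block, gave 54, all higher on the brush, in a fit with hardly any residual degrees of freedom. A common fit of all libraries gave 38 higher and 4 lower. On simulated counts of the same size the test recovered 3% of genes changed 4-fold, 50.7% at 16-fold and 97% at 64-fold. The simulated libraries shared a pooled profile and held none with few genes, so these rates are not those of the real libraries. Fitted changes beyond 64-fold, such as those of WFDC1 and COL1A1, did not pass in the real libraries.

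Endothelial genes did not pass between the brush and the wire. Of 34 measured members 19 had a positive fold change, with a median of 0.09, a mean of -0.02 and an upward camera test (limma's test of a gene list against all other genes) at adjusted p = 0.402. PECAM1, an adhesion molecule of endothelial cells, platelets and white cells, averaged 252.1 ± 333.4 CPM on the brush (SD, n = 10) and 289.5 ± 191.1 CPM on the wire (n = 4). CDH5, the cadherin of endothelial junctions, averaged 33.1 ± 48.6 against 27.1 ± 29.2 CPM. TEK, the angiopoietin receptor, averaged 27.5 ± 29.2 against 26.9 ± 19.3 CPM, and KDR, a VEGF receptor, 134.9 ± 207.1 against 278.1 ± 341.4 CPM. Each of these genes had an edgeR adjusted p of 0.9998. The endothelial score, the mean of log2(CPM + 1) over the list, was 4.54 ± 0.909 on the brush and 4.02 ± 1.76 on the wire. It was 4.42 ± 0.0867 in aorta (n = 4) and 2.57 ± 2.09 in blood (n = 3), where blood 2 had 0.170 and the others 3.56 and 3.99. The brush minus wire difference of 0.52 was within the spread between libraries (exact two-sided permutation p = 0.465 over 1001 splits, and 0.368 when permuted within pig and organ). It was -0.64 in pig 243K and 1.68 in pig 248K, and -0.03 without wire 2. Wires 2 and 3, with 9416 and 8870 genes at fixed depth, were both of pig 248K. Wires 1 and 4, with 14958 and 17671 genes, were of pig 243K, so pig and wire library cannot be told apart. With a pseudocount of 0.1 the score difference over all brush and wire libraries was 1.095 (exact permutation p = 0.377) and with a pseudocount of 5 it was 0.178 (exact permutation p = 0.709). Arterial endothelial genes had a median of 0.64 and a camera adjusted p of 0.0203, which was 0.0563 with the pig as a block (adjusted p = 0.635 with an estimated correlation). HEY2, a Notch target of arteries, averaged 68.0 ± 75.3 against 14.5 ± 5.04 CPM.

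**Figure D1:**
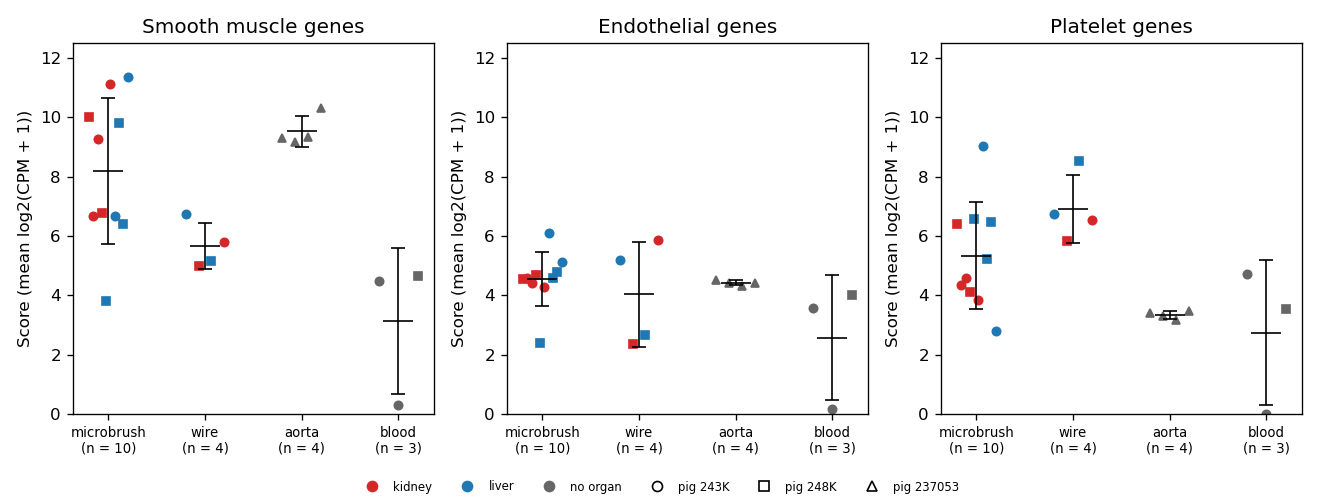
Score of the smooth muscle, endothelial and platelet gene lists (vertical axis, mean of log2(CPM + 1) over a list's members) in each library by group, with colour for the organ, marker shape for the pig, and bars at the group mean ± SD. The mean smooth muscle score was 8.18 on the brush and 5.66 on the wire, while the mean endothelial score was 4.54 and 4.02 and the mean platelet score 5.34 and 6.91.

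Of the 21 gene lists, 11 passed camera at its preset correlation, and 0 passed with a correlation estimated from the data or by fry. The smooth muscle list was higher on the brush (adjusted p = 7.82e-06, and adjusted p = 0.615 with an estimated correlation), with 16 of 22 members passing when adjusted over the list alone and 0 over all genes. The matrix list was higher as well (adjusted p = 7.92e-07; adjusted p = 0.462 with an estimated correlation), with 6 members passing when adjusted over the list alone. HOX genes, which record position along the body, had a median of 0.73 (adjusted p = 0.00387; adjusted p = 0.635 with an estimated correlation) and 2 members passing when adjusted over the list alone. Without microbrush 4 this call ended (adjusted p = 0.115). The HOX score was 0.911 and 0.119 in wires 2 and 3, with 9416 and 8870 genes at fixed depth, and 2.80 and 3.17 in wires 1 and 4, with 14958 and 17671 genes. HOXA10 averaged 13.2 ± 17.6 CPM on the brush and had no count in the 4 wire libraries, which makes it at least 55.9-fold higher against a floor of 3 counts over the group. Lists of blood cells ranked lower on the brush. Erythroid genes had a median of -0.998 (adjusted p = 2.67e-09, and adjusted p = 0.193 with an estimated correlation), and 4 of 16 were lower when adjusted over the list alone. Platelet genes had a median of -0.89 (adjusted p = 2.97e-12, and adjusted p = 0.220 with an estimated correlation).

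The neutrophil list had a median of -0.76 (adjusted p = 1.74e-05), the T and NK cell list -0.63 (adjusted p = 0.00025) and the B cell list -0.05, or 0.24 under RLE scaling (adjusted p = 0.0146). In these lists adjusted p = 0.397, 0.615 and 0.635 with an estimated correlation. Interferon response genes had a median of -0.76 (adjusted p = 2.72e-07) and mitochondrially encoded genes -0.43 (adjusted p = 0.00124), with adjusted p = 0.397 and 0.635 with an estimated correlation. Lists of the organs themselves did not pass. Hepatocyte genes had a median of 0.26 (adjusted p = 0.461), kidney tubule and podocyte genes -0.03 with an upward test (adjusted p = 0.771), and liver sinusoid endothelial genes -0.06 (adjusted p = 0.573). Endothelial activation genes had a median of 0.07 with a mean of -0.15 and a downward test (adjusted p = 0.166). Shear and haemostasis genes had a median of 0.06 with a downward test (adjusted p = 0.361), and monocyte and macrophage genes -0.18 (adjusted p = 0.361). Immediate early genes had a median of 0.30 with a downward test (adjusted p = 0.661), heat shock genes 0.46 (adjusted p = 0.771) and proliferation genes 0.72 (adjusted p = 0.0546). With RLE in place of TMM scaling the median of all genes moved from 0.17 to 0.60, and the medians of the monocyte, kidney tubule and liver sinusoid lists turned positive. Those of the erythroid, neutrophil, T and NK cell and mitochondrially encoded lists moved to -0.47, -0.40, -0.14 and -0.06.

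Haemoglobin genes made up a smaller share of the brush libraries than of the wire libraries. The share was 0.114% ± 0.105 of counts on the brush (SD, n = 10), 1.15% ± 1.35 on the wire (n = 4), 0.00193% ± 0.00106 in aorta (n = 4) and 2.59% ± 2.25 in blood (n = 3). The medians were 0.0718%, 0.637%, 0.00193% and 3.69%. The difference of -1.03 percentage points passed the exact two-sided permutation test (p = 0.0030, and p = 0.00694 when permuted within pig and organ). It was -0.221 in pig 243K and -1.85 in pig 248K, each with exact p = 0.0476, the smallest that 5 against 2 libraries allow. The wires of pig 248K were wires 2 and 3, those with the fewest genes at fixed depth, so the pigs differ in wire libraries too. In kidney alone the share difference was -1.51 and did not pass (exact p = 0.0952), and in liver alone -0.556 (exact p = 0.0476). Without wire 2, whose share was 3.13% (Wilson 95% interval 3.10% to 3.15%), it was -0.375 (exact p = 0.0105). Blood 2 had no haemoglobin count among its 5634 counts, which allows a share of up to 0.0533%. Such intervals and limits cover counting error only.

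**Figure D2:**
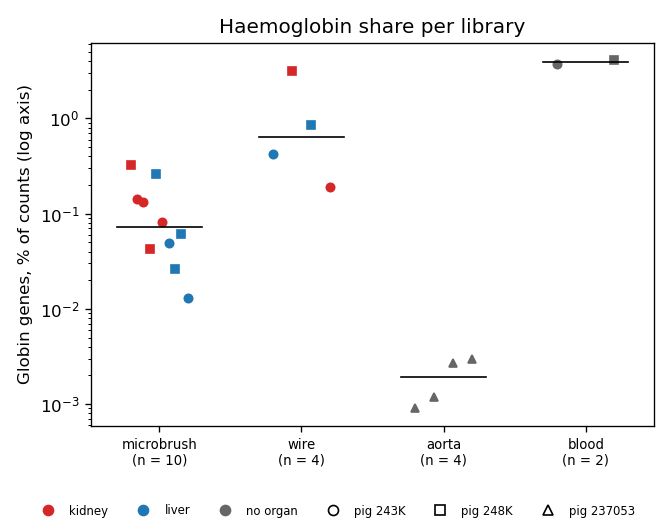
Percent of each library's counts in haemoglobin genes (vertical log axis) by group, with colour for the organ, marker shape for the pig and a line at the group median. Shares of the brush libraries ran from 0.0129% to 0.328% and those of the wire libraries from 0.190% to 3.13%; blood 2, with a share of 0, is not drawn.

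Likeness to aorta over blood was the Spearman correlation across 17616 genes with the mean aorta profile minus that with the mean blood profile. It was 0.0299 ± 0.118 on the brush (SD, n = 10) and -0.0835 ± 0.134 on the wire (n = 4), against 0.271 ± 0.0393 in aorta and -0.199 ± 0.113 in blood. The aorta and blood libraries are part of the mean profiles they were compared with, which moves their values apart. Brush and wire libraries are in neither profile. Genes are not independent replicates, and the difference of 0.113 between brush and wire libraries did not exceed their spread (exact two-sided permutation p = 0.147). At a fixed depth of 1000000 counts the brush libraries held 15439.5 ± 5007 genes and the wire libraries 12729 ± 4292 (difference 2711, exact two-sided permutation p = 0.365). The difference was -858.5 in pig 243K, 1424.5 without wire 3, 1606.5 without wire 2 and 4358 without wire 4. Wires 2 and 3 were both of pig 248K, so pig and wire library cannot be told apart here. Aorta held 18841 ± 157 genes and blood 18132 ± 955 (n = 2). The smooth muscle score was 8.18 ± 2.46 on the brush and 5.66 ± 0.789 on the wire (exact permutation p = 0.0869, adjusted p = 0.598 over 21 lists). The matrix score was 5.82 ± 1.81 against 3.27 ± 1.98 (exact permutation p = 0.0290, adjusted p = 0.399).

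The brush libraries were next compared with whole blood, the fluid around the device. Smooth muscle and matrix genes stood far above their blood level on the brush, with positive fold changes in all 22 and all 19 measured members and medians of 5.25 and 4.68 (log2). ELN, the elastin of arterial walls, averaged 4899 ± 7187 CPM on the brush (SD, n = 10) and 0.196 ± 0.340 CPM in blood (n = 3). MYH11 averaged 33420 ± 45030 against 6.85 ± 6.61 CPM, and COL1A1 averaged 8027 ± 14760 against 6.67 ± 6.92 CPM. By camera the smooth muscle list had adjusted p = 2e-61 and the matrix list adjusted p = 3.41e-41. With an estimated correlation both had adjusted p = 0.00729, and by fry adjusted p = 0.114 and 0.0872. Without blood 2 and microbrush 4 the smooth muscle call with an estimated correlation ended (adjusted p = 0.0676), the matrix list had adjusted p = 0.0371, and the arterial endothelial list passed with an estimated correlation (adjusted p = 0.0336). Adjusted over the list alone, 20 smooth muscle and 12 matrix members were higher, although 0 were over all genes. HBB averaged 1971 ± 2476 CPM on the brush and 32080 ± 28900 CPM in blood, and PTPRC, the CD45 antigen of white cells, 512.4 ± 465.4 against 2477 ± 2556 CPM.

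Endothelial genes had a median of 2.07 against blood, with 32 of 34 members positive (camera adjusted p = 1.26e-09; adjusted p = 0.239 with an estimated correlation), and 0 passed when adjusted over the list alone. KDR averaged 261.8 ± 441.2 CPM on the brush and 16.01 ± 14.6 CPM in blood, and TIE1, an endothelial receptor kinase, 69.4 ± 130.3 against 2.85 ± 2.50 CPM. Arterial endothelial genes had a median of 2.51 (adjusted p = 1.12e-08; adjusted p = 0.239 with an estimated correlation). Platelet genes had a median of 3.97 (adjusted p = 1.29e-09, and adjusted p = 0.239 with an estimated correlation), with 7 of 14 members higher when adjusted over the list alone. PPBP, a chemokine stored in platelets, averaged 941.4 ± 1802 against 44.5 ± 51.8 CPM. Mitochondrially encoded genes (median 1.32, adjusted p = 9.05e-15), immediate early genes (1.49, adjusted p = 1.42e-06) and shear and haemostasis genes (0.97, adjusted p = 0.0358) also ranked higher. These had adjusted p = 0.207, 0.371 and 0.507 with an estimated correlation. T and NK cell genes (-1.23, adjusted p = 9.81e-07) and B cell genes (-0.61, adjusted p = 0.0119) ranked lower, with adjusted p = 0.379 and 0.608 with an estimated correlation. Neutrophil genes (-0.29, adjusted p = 0.0017) and erythroid genes (-0.64, adjusted p = 0.0215) ranked lower too, although their medians were 0.26 and 0.02 under RLE scaling. Here adjusted p = 0.507 and 0.622 with an estimated correlation. Kidney tubule genes had a median of 0.47 and a downward test (adjusted p = 0.0358, and adjusted p = 0.660 with an estimated correlation), which ended without blood 2 and microbrush 4 (adjusted p = 0.469). Without these 2 libraries the interferon (-2.21, adjusted p = 1.25e-07) and proliferation lists (-0.96, adjusted p = 0.0066) passed, with adjusted p = 0.314 and 0.360 with an estimated correlation. Medians were then 4.42 for the smooth muscle, 4.32 for the matrix, 2.54 for the platelet, 0.595 for the mitochondrially encoded, 1.53 for the endothelial and 1.86 for the arterial endothelial list. They were -2.05 for the T and NK cell, -1.47 for the B cell, -0.92 for the neutrophil and -1.32 for the erythroid list.

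Of 16874 genes, 2 passed edgeR's test, both lower on the brush, and 709 had an unadjusted p under 0.05. DESeq2 called 402 higher and 8 lower, limma voom 242 higher and 392 lower, and counts summed per pig 592 higher and 456 lower. The summed fit left 1 residual degree of freedom, so it measured the spread between pigs poorly. In its sums blood 2 added only 5634 counts, and deep libraries weighed most. PRSS56, a serine protease, was lower by the test (-4.95, SE 1.08, adjusted p = 0.0361) at 7.69 ± 18.2 against 234.4 ± 405.7 CPM, but its fold change was 4.82 without blood 2. The other gene has no name in the files. The count was 4 without blood 1 or blood 3 and 3 without blood 2, and 0 with the pig as a block. RLE scaling moved the median of all genes from 0.40 to 0.84.

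Surgically removed aorta was the vessel reference, and the mean levels of the main smooth muscle genes on the brush differed from it by less than the spread between libraries. MYH11 averaged 23800 ± 29500 CPM on the brush (SD, n = 10) and 26040 ± 9749 CPM in aorta (n = 4), with an edgeR log2 fold change of -0.13 (SE 1.15, adjusted p = 0.9998). ACTA2 averaged 3505 ± 4869 against 2376 ± 1442 CPM. The smooth muscle score was 8.18 ± 2.46 on the brush and 9.52 ± 0.522 in aorta (exact two-sided permutation p = 0.313). The brush libraries were not alike in it. Microbrush 3, 4, 6, 8 and 10 scored 3.81 to 6.78, below aorta at 9.17 to 10.30, where the wires scored 4.99 to 6.72. Microbrush 1, 2, 5, 7 and 9 scored 9.27 to 11.34. The smooth muscle list had a median of 0.13 with a downward test (camera adjusted p = 0.112), and the matrix list 0.31 with a downward test (adjusted p = 0.465), while under RLE scaling these medians were -0.48 and -0.24. Globin genes rose on the brush relative to aorta. HBB averaged 1325 ± 1584 against 16.9 ± 11.7 CPM (log2 fold change 6.29, SE 1.30, adjusted p = 0.0308). HBM, a further globin, averaged 44.4 ± 37.6 against 0.817 ± 1.31 CPM (5.72, SE 1.22, adjusted p = 0.0469). PARVB, an adaptor of focal adhesions that link cells to matrix, rose as well, at 153.1 ± 247.5 against 0.460 ± 0.479 CPM (8.21, SE 1.58, adjusted p = 0.0169). These 3 calls ended when any 1 aorta library was left out, with adjusted p up to 0.275 for HBB, 0.339 for HBM and 0.125 for PARVB.

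Lower on the brush than in aorta was APOE, a lipid carrier made by liver and macrophages, at 3.79 ± 4.64 against 155.9 ± 95.9 CPM (-5.33, SE 0.91, adjusted p = 0.00712). The transcription factors CEBPD and ZBTB16 fell as well, CEBPD to 9.63 ± 4.87 against 99.7 ± 35.6 CPM (-3.36, SE 0.63, adjusted p = 0.0138) and ZBTB16 to 59.7 ± 30.1 against 588.1 ± 138.9 CPM (-3.30, SE 0.63, adjusted p = 0.0149). DHX37, an RNA helicase of ribosome assembly, fell too (-3.13, SE 0.64, adjusted p = 0.0303). PCDHB7, a protocadherin, had no count in the 10 brush libraries and averaged 22.5 ± 7.12 CPM in aorta, at least 210.3-fold higher against a floor of 3 counts over the group (adjusted p = 0.00109). The call of PCDHB7 held without each aorta library, while those of ZBTB16 and DHX37 ended each time (adjusted p up to 0.0864 and 0.517), that of CEBPD without aorta 1, 3 or 4 (up to 0.174) and that of APOE without aorta 4 (0.0687). In all, 21 of 16776 genes passed, 10 higher and 11 lower on the brush, and 805 had an unadjusted p under 0.05. The count was 8, 10, 12 and 7 without aorta 1, 2, 3 and 4. DESeq2 called 150 higher and 61 lower on the brush, and limma voom 241 higher and 516 lower. Without microbrush 4 edgeR called 9 higher and 27 lower. All aorta libraries came from a pig that gave no other library, so pig and group cannot be told apart here.

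Platelet genes had a median of 4.34 against aorta, with positive fold changes in all 14 members and 9 passing when adjusted over the list alone (camera adjusted p = 2.17e-11; adjusted p = 0.268 with an estimated correlation). TUBB1, the platelet tubulin, averaged 1665 ± 2774 CPM on the brush and 23.7 ± 9.84 CPM in aorta. Interferon response genes had a median of 1.49 (adjusted p = 6.06e-12; adjusted p = 0.268 with an estimated correlation), with 4 of 15 passing when adjusted over the list alone, and IFIT1 averaged 359.1 ± 388.4 against 39.3 ± 7.94 CPM. Endothelial genes had a median of 0.91 and 24 of 32 positive members (adjusted p = 4.64e-05; adjusted p = 0.5263 with an estimated correlation). Within this list PECAM1 averaged 308.4 ± 445 against 46.9 ± 11.4 CPM, KDR 166.4 ± 269.8 against 11.13 ± 1.83 CPM, and CDH5 41.0 ± 65.5 against 20.3 ± 6.63 CPM. Heat shock genes (1.18, adjusted p = 0.00199) and immediate early genes (0.99, adjusted p = 0.00429) also ranked higher, with adjusted p = 0.392 and 0.770 with an estimated correlation. Erythroid genes ranked higher by the test and by their mean of 1.06, though their median was -0.03 (adjusted p = 0.00739, and adjusted p = 0.686 with an estimated correlation). Of 15 members 2 were higher over all genes and 3 when adjusted over the list alone, and without microbrush 4 the list call ended (adjusted p = 0.154). Mitochondrially encoded genes had a median of -1.25 (adjusted p = 1.16e-10) and kidney tubule genes -0.49 (adjusted p = 0.0183). For these adjusted p = 0.338 and 0.827 with an estimated correlation. RLE scaling moved the median of all genes from -0.17 to -0.33 and also turned the medians of the arterial endothelial, endothelial activation and proliferation lists negative. It moved that of the endothelial list to 0.34, of the interferon list to 0.95 and of the heat shock list to 0.58. The endothelial score differed between brush and aorta by 0.12 (exact two-sided permutation p = 0.675).

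Wire against blood showed what the control device itself carried. Platelet genes had positive fold changes in all 13 measured members and a median of 4.35 (log2; camera adjusted p = 1.91e-18; adjusted p = 0.5004 with an estimated correlation), with 0 passing when adjusted over the list alone. GNG11, a G protein subunit abundant in platelets, averaged 649.6 ± 590.2 CPM on the wire (SD, n = 4) and 12.2 ± 16.7 CPM in blood (n = 3), and PPBP 971.6 ± 944.8 against 46.2 ± 51.9 CPM. HBB differed by less than its spread, at 24540 ± 25100 and 33890 ± 29920 CPM (log2 fold change -0.47, SE 2.29). ELN averaged 993 ± 1217 CPM on the wire against 0.198 ± 0.344 CPM in blood (11.48, SE 3.05) and MYH11 536.6 ± 630.2 against 7.41 ± 7.39 CPM. Smooth muscle genes had a median of 1.74 (adjusted p = 1.86e-07, and adjusted p = 0.578 with an estimated correlation). Matrix genes had a median of 2.37 (adjusted p = 4.92e-05), with 3 members higher when adjusted over the list alone, and endothelial genes 1.83 (adjusted p = 0.0044). Both had adjusted p = 0.837 with an estimated correlation.

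Mitochondrially encoded genes had a median of 1.87 in the wire libraries against blood (adjusted p = 1.47e-16, and adjusted p = 0.5004 with an estimated correlation). Immediate early genes had a median of 1.08 (adjusted p = 0.0418) and proliferation genes -0.66 (adjusted p = 0.0121). Interferon response genes had a median of -0.66 and an upward test (adjusted p = 0.00559), and kidney tubule genes a median of 0.24 and a downward test (adjusted p = 0.0418). Each of these last 4 lists had adjusted p = 0.837 with an estimated correlation. With the pig as a block the interferon and kidney tubule calls ended (adjusted p = 0.0742 and 0.156), and the arterial endothelial list (median 1.55) passed at adjusted p = 0.0202 where it had 0.185, or 0.841 with an estimated correlation, without the block. Without blood 2 the interferon test reversed to downward (-1.36, adjusted p = 1.87e-06) and the kidney tubule call ended (-0.11, adjusted p = 0.461). The T and NK cell (-1.48, adjusted p = 9.77e-06) and B cell lists (-1.19, adjusted p = 0.0287) then passed. With an estimated correlation the interferon, T and NK cell and B cell lists had adjusted p = 0.506, 0.279 and 0.506. Without blood 2 the medians of the platelet, matrix, smooth muscle and endothelial lists were 3.68, 1.77, 1.31 and 1.41, and those of the mitochondrially encoded, immediate early and proliferation lists 1.16, 0.496 and -1.51. Of 14483 genes 0 passed edgeR's test, with 148 at an unadjusted p under 0.05, while DESeq2 called 159 and limma voom 78. Simulated changes were recovered at 0% even at 64-fold, and 8 genes passed without blood 2. RLE scaling moved the median of all genes from 0.32 to 0.54 and that of the interferon list to -0.25.

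Aorta against blood set the references of the design side by side. Matrix genes stood higher in aorta, with positive fold changes in all 19 measured members and a median of 3.19, and 3 of them passed over all genes. ELN rose to 1987 ± 1072 CPM in aorta (SD, n = 4) from 0.316 ± 0.547 CPM in blood (n = 3; log2 fold change 11.86, SE 3.10, adjusted p = 0.0176 by edgeR). DCN, a collagen-binding proteoglycan, rose to 97.5 ± 88.4 from 1.32 ± 1.27 CPM (5.67, SE 1.44, adjusted p = 0.0134). COL5A1, a fibrillar collagen (11.44, SE 3.00, adjusted p = 0.0185), and LAMA4, a laminin of vessel basement membranes (7.80, SE 2.09, adjusted p = 0.0210), rose as well. HBB fell by 10.75 (SE 2.99, adjusted p = 0.0295), at 29.99 ± 21.5 against 51730 ± 46540 CPM, and ALAS2 fell by 8.74 (SE 2.30, adjusted p = 0.0191). Single genes of white cells fell too. Among them were STAT4, a cytokine signal transducer of T and NK cells (-5.28, SE 1.05, adjusted p = 0.000669), and IRF7, a driver of interferon genes (-5.40, SE 1.44, adjusted p = 0.0210). So was PADI4, a citrullinating enzyme of neutrophils (-2.81, SE 0.76, adjusted p = 0.0236). KLF2, a transcription factor of endothelium and resting T cells, was at 7.55 ± 1.45 CPM in aorta and 152.8 ± 146 CPM in blood (-4.36, SE 1.22, adjusted p = 0.0318). Each of the calls in this comparison named so far ended without aorta 4, at adjusted p from 0.0634 (DCN) to 0.485 (KLF2), and some ended without aorta 1, 2 or 3 (KLF2 0.588 without aorta 3), blood 1 (PADI4 0.390) or blood 3 (LAMA4 0.164). PCDHB7 and ADIRF, which had no count in blood, were at least 55.1-fold and 42.7-fold higher in aorta (adjusted p = 0.000189 for both) and passed without each library in turn. The aorta pig gave no blood library, so tissue and pig cannot be told apart here, and leaving out single libraries does not test the pig. PCDHB7 also had no count in the brush libraries, which came from the same pigs as blood.

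Of 16046 genes, 239 passed, 158 higher and 81 lower in aorta, and 1803 had an unadjusted p under 0.05. MYH11, at 45980 ± 19370 against 11.06 ± 10.69 CPM, just missed the test (11.86, SE 3.58, adjusted p = 0.0577), and COL1A1 had an adjusted p of 0.0981. The count moved with single libraries: it was 35 without aorta 3 and 47 without aorta 4, all of them higher in aorta, 90 without blood 1, 1.2e+02 without aorta 1 and 123 without aorta 2. Without blood 2 it was 4875, 1677 higher and 3198 lower, and MYH11 (11.55, adjusted p = 2.73e-16) and COL1A1 (7.62, adjusted p = 1.575e-13) passed. Smooth muscle genes had a median of 4.66, with 22 of 22 positive and 12 higher when adjusted over the list alone (camera adjusted p = 1.43e-10; adjusted p = 0.948 with an estimated correlation). Of the matrix list 3 passed over all genes and 14 when adjusted over the list alone (adjusted p = 2.5e-09, and 0.0281 by fry; adjusted p = 0.948 with an estimated correlation). Mitochondrially encoded genes (2.24, adjusted p = 0.000766) ranked higher and neutrophil genes (-0.72, adjusted p = 0.000425) lower, with 4 members of the latter lower when adjusted over the list alone. Both of these lists had adjusted p = 0.948 with an estimated correlation. The T and NK cell list (-1.79, adjusted p = 0.0525), the B cell list (-1.21, adjusted p = 0.368) and the monocyte and macrophage list (0.68, adjusted p = 0.459) did not pass. Without blood 2, 12 lists passed, among them the T and NK cell (adjusted p = 1.04e-09), B cell (adjusted p = 7.58e-07), interferon (adjusted p = 7.6e-18), erythroid (adjusted p = 1.22e-07), arterial endothelial (adjusted p = 1.15e-06) and endothelial lists (adjusted p = 0.0188). In that order these had adjusted p = 0.226, 0.246, 0.186, 0.186, 0.186 and 0.259 with an estimated correlation, and 0 lists passed with it. PECAM1 averaged 82.1 ± 21.2 CPM in aorta and 110.6 ± 99.9 CPM in blood, and CDH5 35.2 ± 10.3 against 16.3 ± 19.97 CPM.

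The kidney and the liver brush libraries were then set against each other. HOX genes had positive fold changes toward the kidney in all 21 measured members, with a median of 1.495 (log2) where the median of all genes was 0.50. HOXA10 averaged 28.6 ± 19.7 CPM in the kidney libraries (SD, n = 5) and 1.93 ± 2.64 CPM in the liver libraries (n = 5), and HOXC6 19.3 ± 13.1 against 0.833 ± 1.19 CPM. COMP and TNC, glycoproteins of the extracellular matrix, averaged 158.6 ± 202.5 against 4.15 ± 7.79 CPM and 452.7 ± 485.9 against 50.3 ± 33.3 CPM. Platelet genes lay toward the liver in all 13 members, with a median of -2.27 and PPBP at 96.1 ± 86.8 against 995.3 ± 1334 CPM. Endothelial genes had a median of -0.58, with KDR at 37.8 ± 23.9 against 257.6 ± 301.7 CPM and PECAM1 at 100.8 ± 75.7 against 458 ± 502.6 CPM. Under RLE scaling the endothelial median was -0.12, and the endothelial score differed by -0.095 (exact two-sided permutation p = 0.865).

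By edgeR 0 of 15013 genes passed in this comparison, with 238 at an unadjusted p under 0.05, 223 of them lower in the kidney libraries. DESeq2 called 66, 2 higher and 64 lower in the kidney libraries, and limma voom 0. DESeq2 gave no adjusted p to 13971 of the genes, so its calls were adjusted over fewer genes than those of edgeR. Pig 243K alone gave 901 genes, 870 of them higher in the kidney libraries, and pig 248K alone gave 0. The liver libraries of pig 243K were microbrush 6 and 9, with 10765 and 13082 genes at fixed depth. Its kidney libraries had 15756 to 19006, so organ and number of detected genes cannot be told apart in this count. The smallest p-values belonged to COMP (5.19, SE 1.42), TNC (3.17, SE 1.04), HOXC6 (4.53, SE 1.53) and IGFBP5 (2.47, SE 0.86) toward the kidney, and to TWF1 (-4.39, SE 1.11), PROS1, SNAP23 and ITGA2 toward the liver, with an adjusted p of 0.9998. Camera passed 9 lists and 0 with an estimated correlation. The HOX list (adjusted p = 1.15e-07), the T and NK cell list (1.06, adjusted p = 0.00203), the kidney tubule list (1.17, adjusted p = 0.00154) and the hepatocyte list (0.68, adjusted p = 0.043) ranked toward the kidney. In that order adjusted p = 0.529, 0.704, 0.704 and 0.818 with an estimated correlation. The platelet list ranked toward the liver (adjusted p = 1.15e-07), with 4 members passing when adjusted over the list alone. So did the interferon list (-1.01, adjusted p = 2.76e-07), the endothelial list (adjusted p = 1.49e-05), the activation list (-0.94, adjusted p = 0.00203) and the heat shock list (-0.16, adjusted p = 0.0045). Each of these 5 had adjusted p = 0.529 with an estimated correlation. The HOX score was 3.87 ± 0.238 in the kidney and 1.86 ± 1.45 in the liver libraries (exact two-sided permutation p = 0.0159 over 252 splits, adjusted p = 0.333 over 21 lists). The lowest scores were those of the liver libraries with the fewest genes. Liver microbrush 4, 6 and 9 scored 0, 1.40 and 1.28 at 3749, 10765 and 13082 genes at fixed depth, while liver microbrush 7 and 8 scored 3.58 and 3.05 at 18907 and 18255 genes. The kidney libraries scored from 3.54 (microbrush 1) to 4.204 (microbrush 2), and the fewest genes among them were 15756 (microbrush 5). The hepatocyte call ended without microbrush 4 (adjusted p = 0.0703), while the matrix (adjusted p = 0.0427), B cell (adjusted p = 0.011) and immediate early lists (adjusted p = 0.0341) passed, with adjusted p = 0.593, 0.515 and 0.593 with an estimated correlation. With the pig as a block the arterial endothelial and matrix lists passed, both at adjusted p = 0.0198, where both had adjusted p = 0.925 with an estimated correlation without the block. RLE scaling moved the median of all genes to 0.83, that of the arterial endothelial list from -0.34 to 0.35 and those of the interferon, activation and heat shock lists to -0.41, -0.57 and -0.04.

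Whether the brush minus wire difference itself differed between kidney and liver was tested as an interaction. MYH11 had an interaction of 1.85 (log2, SE 2.21), COL1A1 of 0.25 (SE 2.01), HBB of 0.13 (SE 1.81) and PECAM1 of -1.52 (SE 1.59), each with an edgeR adjusted p of 1. TNC (5.73, SE 1.83) and STOML1 (-12.44, SE 3.44) were among the smallest p-values. Of 17809 genes 0 passed, with 525 at an unadjusted p under 0.05, while DESeq2 called 2 and limma voom 0. Each organ had 2 wire libraries. T and NK cell genes (median 0.79) and mitochondrially encoded genes (-0.31) passed camera, each with adjusted p = 0.0232 and adjusted p = 0.995 with an estimated correlation. With the pig as a block the endothelial (median -1.22, adjusted p = 0.0511 without and 0.00366 with the block), B cell (adjusted p = 0.0225) and immediate early lists (adjusted p = 0.0308) passed too. Without microbrush 4 these lists passed as well (adjusted p = 0.0431, 0.0141 and 0.0356), as did the neutrophil list (adjusted p = 0.0431). Each of these 4 then had adjusted p = 0.963 with an estimated correlation, and with all libraries and no block 0.995. RLE scaling moved the median of all genes from 0.18 to 0.35, that of the endothelial list to -0.83 and that of the mitochondrially encoded list to -0.13.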

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

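The tests of the smooth muscle, haemoglobin and PECAM1 patterns were chosen only after the result was seen; the splits of the libraries and the search for libraries far from their group were planned. After their outcomes were known, 3 rules were revised: those for whole blood on the wires and for PECAM1 and KDR with CDH5 had first argued against the explanation and now leave it open, and splits with a real count of 0 are no longer read as a test. In 84 groups of libraries (28 measures in the microbrush, wire and aorta groups), 11 had a highest or lowest library set apart by a gap large against the range of its group; chance gives such a gap in about 1 in 20 groups. Microbrush 4 was set apart in this way below the other 9 microbrush libraries in 5 scores: endothelial 2.41 (others 4.28 to 6.09), arterial endothelial 0.56 (4.39 to 6.11), shear and haemostasis 1.93 (4.24 to 4.94), monocyte and macrophage 1.17 (3.53 to 5.30) and liver sinusoid endothelial 0 (2.22 to 4.69). It was also the lowest brush library, with a smaller gap, in most other scores, such as smooth muscle (3.81), matrix (1.90) and HOX (0). The erythroid, platelet, neutrophil, B cell and interferon scores were exceptions, so its low scores were not particular to endothelial or monocyte genes. Microbrush 9 had an erythroid score of 1.96, below the others at 3.40 to 5.00. Aorta 4 stood apart in 4 measures: 18608 genes at fixed depth (others 18897 to 18952), a smooth muscle score of 10.30 (9.17 to 9.34), a monocyte and macrophage score of 4.72 (4.33 to 4.38) and a liver sinusoid score of 3.98 (4.18 to 4.19). Wire 2 had an interferon score of 5.91 where the other wires had 7.33 to 7.59. A difference between organs in the brush minus wire effect passed camera for T and NK cell genes (median 0.79, adjusted p = 0.0232) and mitochondrially encoded genes (median -0.31, adjusted p = 0.0232), each at the preset correlation over 14 libraries, and each with adjusted p = 0.995 with an estimated correlation.

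Smooth muscle genes had positive fold changes from wire to brush in 21 of 22 members, with a median of 3.40 (log2), although 0 passed over all genes, the list had adjusted p = 0.615 with an estimated correlation, and the score differed with an exact permutation p of 0.0869 (adjusted p = 0.598). If less blood RNA raised every vessel wall marker alike, the smooth muscle and endothelial scores would differ by the same amount; the smooth muscle difference was larger by 2.01 log2 units, but with an exact permutation p of 0.140, so this explanation stays open. Libraries with few genes may also carry the pattern. Among the 9 brush and 2 wire libraries with at least 10000 genes at fixed depth the score difference was 2.41, against 2.52 over all brush and wire libraries. With 2 wires left the difference of 2.41 cannot be told apart from chance (exact permutation p = 0.182, the smallest possible being 0.0182). Sampling of wall cells by the brush is the biological candidate that the design names, and no value here sets it apart from these.

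The haemoglobin share was lower on the brush than on the wire. A single wire library is argued against as the whole source, since the difference was -0.375 percentage points (exact permutation p = 0.0105) without the wire with the highest share. The 2 abundant unnamed identifiers do not account for it either, with a difference of -1.69 when both were left out of the total (exact permutation p = 0.0040). More whole blood on the wires stays open: haemoglobin genes differed by -3.25 log2 units beyond the T and NK cell score (exact permutation p = 0.0250), but that score was 4.12 in aorta, 3.81 on the brush and 4.30 on the wire, a baseline that would hide a small share of blood. Other differences between a brush and a bare wire stay open too, and no biological explanation was tested.

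PECAM1 and KDR are read as endothelial genes, yet across the 14 brush and wire libraries they may follow platelet RNA. Microbrush 9 departed from this for PECAM1, at 369.8 CPM with TUBB1 at 7.7, PPBP at 5 and ITGB3 at 25.7 CPM (scaled over all 21 libraries). Its CDH5 was at 45.8 and its KDR at 0.2 CPM. Microbrush 9 and 6 were the 2 libraries farthest from the median platelet score. PECAM1 rose with the platelet score (Pearson r = 0.736, permutation p = 0.00277, adjusted p = 0.00969 over 7 relations; Spearman rho = 0.736, p = 0.00358, adjusted p = 0.00835; r = 0.924 without the 2 farthest libraries; 0.683 in pig 243K and 0.910 in pig 248K), and KDR did so too (r = 0.924, permutation p = 1e-05, the smallest the draws can give, adjusted p = 7e-05; rho = 0.925, p = 1e-05; r = 0.920 without the 2 farthest; 0.920 and 0.924 in the pigs). With CDH5, a marker of endothelial junctions, PECAM1 had r = 0.048 (permutation p = 0.872, adjusted p = 0.872; rho = 0.284, p = 0.324, adjusted p = 0.454), but r = 0.819 without microbrush 4 and wire 3, and 0.975 in pig 243K against -0.734 in pig 248K, so the low pooled value rests on those libraries and endothelial RNA stays open as a source. KDR with CDH5 had r = -0.27 (permutation p = 0.344, adjusted p = 0.603; rho = -0.033, p = 0.914), 0.313 without the same 2 libraries, and 0.537 and -0.796 in the pigs, which leaves it open as well. Of the 15 measured platelet genes, 3 stand on another list too, and abundant ones were high where KDR was, with TUBB1 at 9731 CPM (scaled over all 21 libraries) and ITGB3 at 2755 CPM in wire 3, beside KDR at 997 CPM and CDH5 at 0.3 CPM, while microbrush 6, with TUBB1 at 8516 CPM, ITGB3 at 2571 CPM and KDR at 809 CPM, had the highest CDH5 (214.7 CPM) and TEK (136.7 CPM).

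The counts of changed genes were set against other splits of the same libraries. For brush against aorta 2 of 100 splits, the real one among them, gave as many as its 21 genes. The highest other gave 535, a split that put microbrush 1, 4, 6 and 8 together. By genes with an unadjusted p under 0.05, 6 of 100 splits reached the real count of 805. For aorta against blood only the real split of 35 gave as many as 239 (highest other 32). So large a count was rare among the splits in these 2 comparisons. All aorta libraries came from 1 pig, however, so the splits cannot exclude a chance difference between animals. Chance cannot be excluded for brush against blood either, with 24 of 100 splits giving 2 genes or more (highest other 7020). For brush against wire (100 of 100 splits, highest other 4906), wire against blood (35 of 35, highest other 3070) and kidney against liver (100 of 100, highest other 1) the real count was 0, which every split reaches, so these counts say nothing about chance. The highest split of brush against wire put microbrush 4 and 6 with wire 2 and 3, that of brush against blood put them with blood 2, and that of wire against blood put blood 2 with wire 2 and 3. Microbrush 4 and 6, at 3749 and 10765 genes, and wire 2 and 3, at 9416 and 8870, had the fewest genes at fixed depth among the brush and wire libraries. Blood 2 had counts for 302 genes. These splits gathered libraries with few detected genes, a structure that the groups do not follow.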

How the results depend on the processing

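The runs without libraries under 5000 detected genes, in each pig or organ for the 4 measures, with the blood profile without blood 2 for the aorta likeness and without 2 abundant unnamed identifiers for the haemoglobin share were chosen after the data were seen; the others were fixed before the data were examined. Of the values of named genes under the alternatives 11283 kept their side of the threshold, 559 passed newly and 127 no longer passed. Genes that passed in neither run are among the 11283, so that number does not measure how stable the calls were. Only genes that passed in the main run could give the 127, and where the main count was 0 no named gene did. A reversed direction was counted only for genes that passed in the main run or under the alternative, which gave 2 values. Sign changes of genes that passed in neither run are among the 11283. Both reversed values belonged to PRSS56, microbrush against blood. Its fold change went from -4.95 to 2.13 with voom quality weights. With a replicate left out it ran from -6.41 (without blood 1) to 4.82 (without blood 2). Where no cause is named, the cause was not tested. Genes changed under DESeq2 numbered 1.0e+02 (brush against wire; 96 up, 5 down), 410 (brush against blood; 402 up, 8 down), 211 (brush against aorta), 159 (wire against blood), 1503 (aorta against blood), 66 (kidney against liver) and 2 (interaction); main counts were 0, 2, 21, 0, 239, 0 and 0. With limma voom they numbered 634 for brush against blood (242 up, 392 down) and 757 for brush against aorta (241 up, 516 down). They numbered 78 for wire against blood and 2708 for aorta against blood (931 up, 1777 down). A common fit of all 21 libraries gave 42, 62, 55, 3, 70 and 1 in the first 6 of these comparisons. RLE scaling gave 6 for brush against blood and 502 (271 up, 231 down, main 158 and 81) for aorta against blood, and 17 (5 up, 12 down, main 10 and 11) for brush against aorta. Without a filter there were 13 (brush against blood), 39 (brush against aorta), 610 (aorta against blood) and 1 (kidney against liver), and with the stricter filter 9 (brush against blood) and 407 (aorta against blood). Leaving out haemoglobin genes gave 9 for brush against blood. DESeq2 left many genes without an adjusted p, so its counts are not over the same genes as those of edgeR. These were 11138 of 16874 genes for brush against blood and 7156 of 16776 for brush against aorta. For wire against blood they were 11851 of 14483 and for kidney against liver 13971 of 15013. An adjusted p under 0.01 left 1 gene for brush against blood, 6 for brush against aorta and 83 for aorta against blood. With the pig as a block, which pairs brush, wire and blood of a pig, brush against blood gave 0, and brush against wire, wire against blood, kidney against liver and the interaction also gave 0. Counts summed per pig gave 54 genes for brush against wire and 1048 (592 up, 456 down) for brush against blood, with 2 pigs on each side. Each of these fits left 1 residual degree of freedom, so the counts are a weak check on the spread between pigs. Pig 248K alone gave 46 for brush against wire and pig 243K alone 901 for kidney against liver. In both, the side with lower levels of most called genes held libraries with few detected genes, so these counts do not separate group from library. Without the libraries under 5000 genes (blood 2, microbrush 4) there were 0 (brush against blood), 36 (brush against aorta), 8 (wire against blood) and 4875 (aorta against blood).

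Leaving out 1 replicate at a time gave 0 for brush against wire, kidney against liver and the interaction, 3 (without blood 2) to 4 for brush against blood, 7 (without aorta 4) to 12 (without aorta 3) for brush against aorta, 0 to 8 (without blood 2) for wire against blood and 35 (without aorta 3) to 4875 (without blood 2) for aorta against blood. The brush minus wire endothelial score ran from -0.0339 (without wire 2) to 1.13 and was -0.64 in pig 243K, aorta likeness from 0.0495 to 0.147, genes at fixed depth from 1424.5 to 4358 and -858.5 in pig 243K, and haemoglobin share from -1.35 to -0.375, with -1.51 in kidney alone (exact permutation p = 0.0952, where the smallest possible is 0.0476). Camera with an estimated correlation passed 0 lists for brush against wire, 2 for brush against blood (main 13) and 0 for each other comparison, and fry passed 0 except 1 for aorta against blood; main counts were 11, 13, 8, 9, 4, 9 and 2. With the pig as a block the interaction gave 5 lists, and without the libraries under 5000 genes it gave 6 and aorta against blood 12. Depth limits blood 2 most, and simulated 64-fold changes were recovered at 40.9% for brush against blood, 0% for wire against blood and 36.4% for aorta against blood. These simulations held no libraries with few genes other than through their depth, so the rates are not those of the real libraries.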

Other observations

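The glucocorticoid-responsive genes and the Y-linked genes were chosen only after the result was seen; the tests between pigs and organs were chosen then too, and none of the tests in this part was planned. CEBPD and ZBTB16, which fell on the brush relative to aorta, are known targets of glucocorticoids, and other such targets lay the same way. With TMM scaling over all 21 libraries KLF15 averaged 11.2 ± 6.88 CPM on the brush (SD, n = 10) and 58.9 ± 17.9 CPM in aorta (n = 4), with a log2 fold change of -2.42 (edgeR adjusted p = 0.309), and FKBP5, a chaperone of the glucocorticoid receptor, 29.8 ± 20.4 against 150.8 ± 42.0 CPM (-2.32, adjusted p = 0.313). Other members of the list, such as DUSP1 (0.78, SE 0.87) and SGK1 (0.65, SE 0.81), lay the other way. The members were settled after their levels had been seen, so no test of the list is given, and the aorta libraries differ from the brush libraries in pig and in the way of collection.

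Y-linked transcripts separated the aorta pig from the others. KDM5D had a total of 1 count over the 4 aorta libraries, against 526 counts over the microbrush libraries (9 of 10 with a count), 87 over the wire libraries (3 of 4) and 175 over the blood libraries (2 of 3). EIF1AY had 0 counts in aorta, 456 in 9 of 10 microbrush libraries, 355 in 4 of 4 wire libraries and 450 in 2 of 3 blood libraries. By edgeR the adjusted p of brush against aorta was 0.0678 for KDM5D and 0.0602 for EIF1AY.

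The brush minus wire difference of 9 measures was compared between the pigs and between the organs in 18 exact tests, and none passed (lowest adjusted p = 0.852). For the endothelial score it was -0.64 in pig 243K and 1.68 in pig 248K (difference -2.32, exact permutation p = 0.280). The wires of pig 248K were wires 2 and 3, those with the fewest genes at fixed depth, so pig and wire library cannot be told apart. Between the pigs themselves, 0 of 15013 genes differed among the microbrush libraries by edgeR, with 39 at an unadjusted p under 0.05.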
